A study of Homo sapiens with 5 samples.

How the data were processed

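Gene expression was measured in LNCaP cells, an established androgen-sensitive human prostate cancer line. Per the labels' protocols, the cells carried retroviral short hairpin RNAs under puromycin selection, either a scrambled control (shControl) or a hairpin against RB1 (shRB). All cells received 10 Gy of ionizing radiation and total RNA was isolated 24 h later with Trizol. Biotin-labelled cDNA was hybridised to single-colour whole-transcript arrays, 2 for shControl and 3 for shRB, with the groups taken from the sample labels. No array of unirradiated cells was used here, so the comparison is between 2 irradiated populations and not between irradiated and resting cells. The labels do not say whether the arrays of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

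The values deposited by the authors are intensities per probe set on a linear scale. The summary method, background correction, normalization between arrays, software and genome build are not given in the sources used here. No deposited intensity lay below 16 and the lowest of each array lay just above it, as would follow from an added constant of 16, and between 1.98% and 4.56% of the probe sets of an array lay within 0.01 of it. Such a constant compresses fold changes of dim genes, so the log2 differences understate their size. The median intensity per array ranged from 26.65 to 28.06. The number of arrays limits the precision.

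The table held 44607 probe sets. Of these, 15835 had 1 gene symbol in the platform annotation, 0 had several and 28772 were unnamed here. Symbols were updated through Entrez identifiers with the NCBI RefSeq gene table of assembly GRCh38.p14, which also gave gene types, chromosomes and the order of neighbouring genes. All 15835 named probe sets matched. No coordinates are printed because no build is named for the deposited values. For the 651 genes with more than 1 probe set, the probe set with the highest mean log2 intensity over all arrays was used. This left 14812 genes, of which 11911 are protein-coding, with no filter on dim genes. BRCA1, CDKN1A and MDM2 were to be reported whatever their values, and are not analysed here because no named probe set carries them. In addition, 1 further gene of that set is not reported here.

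The intensities were log2-transformed without further normalization. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups, no covariates), two-sided, with Benjamini-Hochberg adjustment over the 14812 genes and a threshold of 0.05. All adjusted p-values for single genes come from this test unless another setting is named. The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took RB1, the 12 largest increases and the 12 largest decreases among genes that passed and whose arrays did not overlap between groups, E2F1, KLK3, CCND1 and up to 4 members of each list with the smallest p. It left out uncharacterised loci, small RNAs, open reading frame symbols, XIST and Y-linked genes, which removed 19 of the genes that passed. Genes outside the rule that are named in the closing section were chosen after their values were seen.

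Of 28 gene lists, 27 were tested, since no replication-dependent histone gene was measured. They held 462 measured genes of 827 listed. They cover the RB and E2F family, the cell cycle, DNA repair and its branches, the damage checkpoint, p53 targets, apoptosis, androgen receptor targets, lineage and cell type markers, stress responses, lipid synthesis, respiration, ribosomal proteins, interferon-stimulated genes and inflammatory factors. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists. Alternatives were camera with an estimated correlation and fry, which asks whether the genes of a list move on balance 1 way (directional) or in either direction (mixed).

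The gene test was tested on simulated data, 20 simulations of 14812 genes with 200 of them changed. Genes were drawn independently, with limma's variance for each gene and the same spread in both groups. The real shControl arrays differed more from each other than the shRB arrays did, so the rates may not hold for them. The test called 22.33% of genes changed by 0.5 on the log2 scale, 98.41% of those changed by 1 and 100% of those changed by 2, with a mean of 10.65 unchanged genes called. In 100 simulations with independent genes, camera called the 31 replication genes in 0 at no shift, in 34 at a log2 shift of 0.1 and in 100 at 0.2.

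The alternatives were quantile normalization, subtraction of array medians, leaving out dim genes, averaging the probe sets of a gene, an intensity trend with robust variances, array weights, the replicate number as a block, each probe set on its own, other thresholds and leaving out each array in turn. Removal of the constant of 16, with 4 added before the logarithm, was added after the data had been seen, with and without the intensity trend and robust variances. An estimated correlation after quantile normalization, and without shControl replicate 1 or shRB replicate 1, was also added then. Where leaving out an array left 1 shControl array, the lone array was assumed to vary like the shRB arrays.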

Results

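Transcript levels were measured on 5 arrays of irradiated LNCaP prostate cancer cells, 2 with a control hairpin (shControl) and 3 with a hairpin against RB1 (shRB). The array medians of the deposited intensities were 26.65 and 28.06 in shControl and 27.53, 27.95 and 27.38 in shRB. Across the genes tested, with 1 probe set per gene, log2 intensities of the shRB arrays correlated at r = 0.983 to 0.986. The 2 shControl arrays correlated at r = 0.967, and pairs from different groups at r = 0.955 to 0.970. The first principal component, with 46.0% of the variance, separated the groups, and the second, with 28.7%, separated the 2 shControl arrays from each other.

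RB1, the retinoblastoma tumour suppressor and the target of the hairpin, was measured by probe set 16774690 on chromosome 13. Its log2 intensity was 5.81 and 5.70 in shControl replicates 1 and 2 and 5.16, 5.28 and 5.20 in shRB replicates 1 to 3, so every shRB array lay below both shControl arrays. The means were 5.21 ± 0.06 (SD, n = 3) in shRB and 5.76 ± 0.08 (SD, n = 2) in shControl. This is a log2 difference of -0.54 (SE 0.14, 95% interval -0.86 to -0.23), or 1.46-fold lower. With the apparent constant of 16 taken off the linear values, the shRB level was 0.55 of the shControl level. The difference did not pass limma's test over all genes (adjusted p = 0.0967) and passed when adjusted over the list alone, that of the RB and E2F family. With genes below the median intensity left out, it passed at an adjusted p of 0.0489. The genes flanking RB1, ITM2B (log2 0.16) and RCBTB2 (0.37), and LPAR6, which lies within RB1 (-0.02), did not pass.

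The comparison of shRB with shControl cells addressed which transcripts differ when RB1 is depleted in cells that have received 10 Gy. Among the 14812 genes tested, which leave out unnamed probe sets, the largest decrease was that of TWIST1 and the largest increase that of PCDH7. TWIST1, a transcription factor of the mesenchymal programme, fell by 2.45 on the log2 scale (SE 0.14, adjusted p = 3.24e-05), from 6.67 ± 0.03 (SD, n = 2) to 4.22 ± 0.07 (SD, n = 3), 5.45-fold lower on the deposited scale. That shRB level lies close to the floor of the deposited values, a log2 intensity of 4, and is not shown to be above background, so the fold in transcript level is not known. PCDH7, a protocadherin that mediates cell adhesion, rose by 2.12 (SE 0.16, adjusted p = 0.000106), from 4.73 ± 0.12 to 6.84 ± 0.18, 4.33-fold higher on the deposited scale. Its shControl level was close to that of the median probe set of those arrays, so this fold carries the same limit.

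Other strong decreases were in CRYBG1 (log2 -2.37, adjusted p = 0.000106), TMEM45B (-2.22, adjusted p = 0.000101) and ECHDC1, an ethylmalonyl-CoA decarboxylase (-1.85, adjusted p = 0.000106). GSTA1, a glutathione transferase, changed by -1.77 and the metalloprotease TLL1 by -1.74. S100A10, a partner of annexin A2, changed by -1.51, the scavenger receptor COLEC12 by -1.47, the readthrough transcript CCDC169-SOHLH2 by -1.45 and TARP, a transcript of the T cell receptor gamma locus, by -1.43. The ubiquitin protease family members USP17L12 and USP17L9P both changed by -1.35. They are near-identical copies with intensities equal to 2 decimals, so they cannot be counted as separate genes. The adjusted p-values of these last 8 genes were at most 0.0028. In shRB, CCDC169-SOHLH2 (4.29), ECHDC1 (4.37), S100A10 (4.43) and CRYBG1 (4.67) lay near the floor, so the size of their decreases is as limited as that of TWIST1.

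Among the increases, the ephrin receptors EPHA3 and EPHA6 were 2.95-fold (adjusted p = 0.000485) and 2.83-fold (adjusted p = 0.00194) higher as deposited, or 3.17-fold and 3.35-fold with the constant taken off. EPHA3 reached a log2 intensity of 8.85 ± 0.04 in shRB against 7.29 ± 0.04 in shControl. PCDH20, a further protocadherin, rose by 1.56 on the log2 scale (adjusted p = 0.000513) and LRRC4C, a netrin-G1 ligand of neurons, by 1.53 (adjusted p = 0.00102). RALYL rose by 1.42, the cytochrome oxidase subunit COX7B2 by 1.40, the glucagon gene GCG by 1.26 and butyrylcholinesterase, BCHE, by 1.19, with adjusted p-values of at most 0.00315. In shControl, COX7B2 and PCDH20 were dim (log2 intensity 4.69 and 5.05), so the size of their rises depends on the constant. They were 2.64-fold and 2.95-fold higher as deposited, or 5.36-fold and 4.77-fold with the constant taken off. The metallothionein MT1X (log2 1.21, adjusted p = 0.0182), whose paralogs may share its signal, the antisense transcript FAM13A-AS1 (1.20, adjusted p = 0.034) and the kinase adaptor TAB3 (1.17, adjusted p = 0.0336) also passed.

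**Figure D1:**
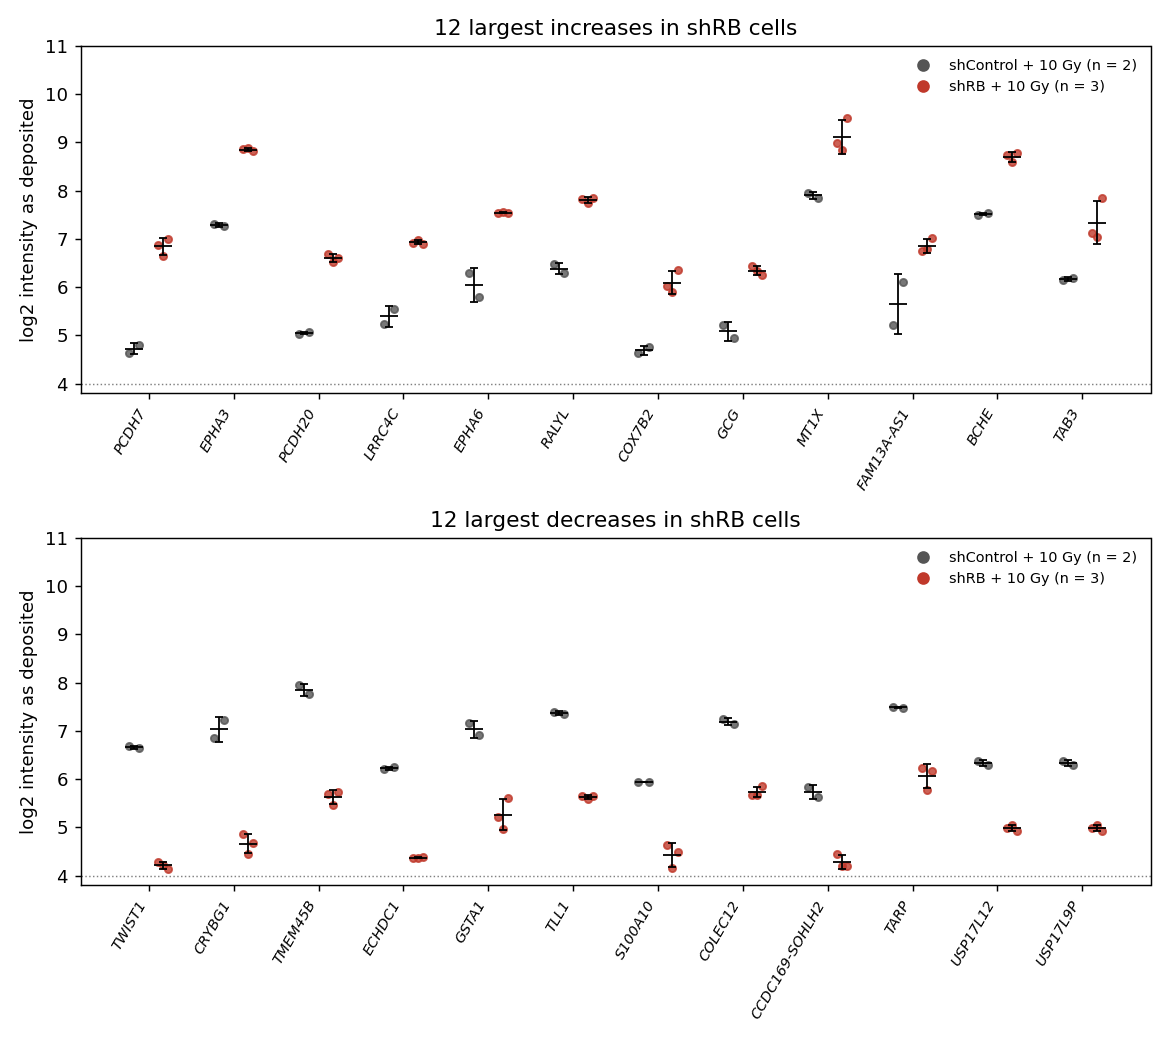
Log2 intensity as deposited (vertical axis) of the 12 largest increases and the 12 largest decreases in shRB cells, with 1 point per array (2 shControl, 3 shRB, all after 10 Gy), bars at the mean ± SD and a dotted line at the floor of 4. TWIST1, CCDC169-SOHLH2, ECHDC1 and S100A10 lie near the floor in shRB, and PCDH7 rises from 4.73 to 6.84.

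In all, 159 of 14812 genes passed, 103 higher and 56 lower in shRB. At least 2-fold changes were seen in 25 of the higher and 28 of the lower genes. Of the 159 genes, all had arrays that did not overlap between groups, as had 5333 genes (36.0%) of those tested, against 20% by chance. With 16 subtracted and 4 added before the logarithm, 4 genes were higher and 9 lower, so the share of increases moved from 64.8% to 30.8%. Of the 32 named genes that had passed, 21 no longer did, among them EPHA6, FN1, SNAI2, GSTA1, PLK3 and BIK. With an intensity trend and robust variances as well, 294 were higher and 156 lower and all 159 genes passed. Without shControl replicate 1 or 2 the test called 411 and 242 genes, and without shRB replicate 1, 2 or 3 it called 28, 22 and 22. In those last 3 fits decreases outnumbered increases, with 12 higher and 16 lower, 9 and 13, and 8 and 14. BCHE did not pass without shRB replicate 3 (adjusted p = 0.0617), MT1X did not pass without any 1 of the shRB arrays, FAM13A-AS1 passed only without shControl replicate 2 and TAB3 passed in none of these 5 fits, with adjusted p-values of up to 0.111, 0.237 and 0.137.

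The cell cycle, named in the study's design text, gave no list past the threshold by camera. Of 31 measured DNA replication and S-phase genes of 51 listed, none passed over all genes or adjusted over the list alone (limma, Benjamini-Hochberg). Positive differences numbered 19 and negative ones 12, with a median of 0.06. No listed DNA polymerase or primase gene had a named probe set. CCNE1, the G1/S cyclin E1 (log2 0.53, adjusted p = 0.112), the helicase subunit MCM4 (0.44, adjusted p = 0.152) and the replication factor GINS2 (0.47, adjusted p = 0.16) did not pass. Of 57 G2 and mitosis genes, none passed either, and 28 had positive and 29 negative differences, with a median of -0.01. TROAP stood at 0.44 (adjusted p = 0.154), CEP55 at -0.46 (adjusted p = 0.176) and CCNA2, cyclin A2, at -0.40 (adjusted p = 0.218). Both lists had a camera adjusted p of 0.52. In the RB and E2F family (16 measured, camera adjusted p = 0.866), none passed over all genes, and E2F3 (0.78, adjusted p = 0.0935) and RB1 passed adjusted over the list alone. E2F1, an activator of S-phase genes, differed by 0.27 (adjusted p = 0.359) and CCND1, cyclin D1, by -0.14 (adjusted p = 0.696).

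DNA repair, the subject of the study's title, gave no list past the threshold by camera. Of 65 measured repair genes of 122 listed, none passed over all genes (limma), and 6 were higher when adjusted over the list alone. They were NTHL1, a base excision glycosylase (log2 0.82, adjusted p over all genes 0.0654), the mismatch repair genes MLH3 (0.63, 0.0945), PMS1 (0.61, 0.0709) and PMS2 (0.59, 0.0965), the Fanconi ubiquitin-conjugating enzyme UBE2T (0.57, 0.0967) and the break-end nuclease MRE11 (0.56, 0.0999). With genes below the median intensity left out, the same 6 genes passed over all genes, at adjusted p-values of 0.0262 to 0.0499. The whole repair list had 39 positive and 26 negative differences, a median of 0.04 and a camera adjusted p of 0.52. Among the negative ones, MUS81 (log2 -0.39, adjusted p over all genes 0.268), NBN (-0.38, 0.213) and APEX1 (-0.30, 0.315) did not pass. By branch, camera gave an adjusted p of 0.216 for mismatch repair (5 measured, median 0.59), 0.52 for the Fanconi (6, 0.13) and base excision (17, 0.16) lists, 0.782 for homologous recombination (25, 0.02) and non-homologous end joining (8, -0.03) and 0.831 for nucleotide excision (4, 0.01).

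The DNA damage checkpoint list (18 measured of 23 listed, without ATM, median 0.17, camera adjusted p = 0.31) had no gene past the threshold over all genes. Adjusted over the list alone, the kinase ATR (log2 0.53), the mediator MDC1 (0.46) and the nucleases DCLRE1A (0.46) and DCLRE1B (0.54) were higher. Among 25 p53 targets (camera adjusted p = 0.52), 1 passed, the kinase PLK3, which rose by 0.84 (adjusted p = 0.0336). Adjusted over the list alone 4 were higher and 1, CCNG2, was lower. Of 42 listed apoptosis genes, 22 were measured (camera adjusted p = 0.52), and no listed caspase gene, FAS or CYCS had a named probe set. Of the 22, 1 passed over all genes and over the list alone, the pro-apoptotic BIK, which rose by 0.77 (adjusted p = 0.0486). BAK1 stood at -0.48 (adjusted p = 0.136) and PMAIP1 at 0.58 (adjusted p = 0.166). Without shControl replicate 1, or without any 1 shRB array, neither PLK3 nor BIK passed, with adjusted p-values of up to 0.208 and 0.24.

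**Figure D2:**
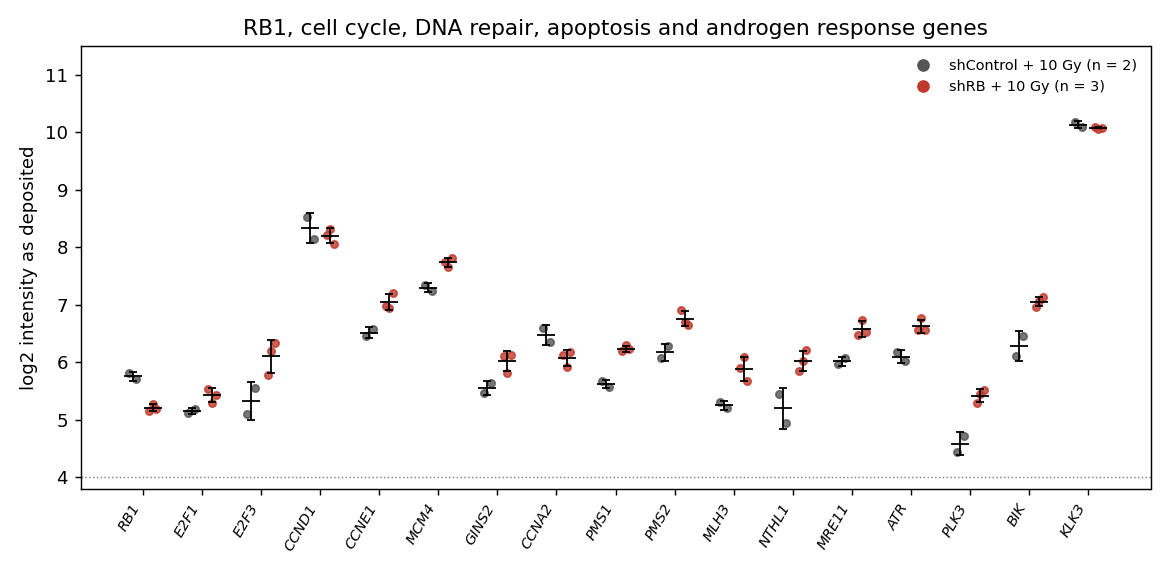
Log2 intensity as deposited (vertical axis) of RB1 and of cell cycle, repair, checkpoint, apoptosis and androgen response genes, with 1 point per array (2 shControl, 3 shRB, all after 10 Gy), bars at the mean ± SD and a dotted line at the floor of 4. RB1 is 5.76 in shControl and 5.21 in shRB, and KLK3 is near 10.1 in both. The repair and checkpoint genes plotted are all higher in shRB, and those that were lower are not shown.

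Prostate lineage lists did not pass by camera. Among 18 androgen receptor targets (camera adjusted p = 0.52), the ubiquitin ligase HERC3 rose by 0.74 (adjusted p = 0.0491) and 3 were higher adjusted over the list alone. HERC3 passed in 1 of the 5 fits without an array, that without shControl replicate 1, and reached an adjusted p of 0.221 without shRB replicate 1. KLK3, which encodes prostate-specific antigen, had a log2 intensity of 10.08 in shRB and 10.13 in shControl (difference -0.05, adjusted p = 0.875). No luminal (16 measured, camera adjusted p = 0.565), basal (8, 0.782) or neuroendocrine (17, 0.991) marker passed over all genes. The neuropeptide genes NTS (0.72, adjusted p = 0.0552) and GRP (0.60, adjusted p = 0.0935) were higher when adjusted over the neuroendocrine list alone.

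The mesenchymal and stromal markers moved in both directions (12 measured, camera adjusted p = 0.512). TWIST1, the extracellular matrix gene FN1 (log2 intensity 9.37 against 10.37, adjusted p = 0.0103) and the intermediate filament gene VIM (log2 -0.81, adjusted p = 0.0452) fell, while SNAI2, a repressor of epithelial genes, rose by 1.10 (adjusted p = 0.0151). Adjusted over the list alone, 3 were higher and 3 lower. FN1 and SNAI2 did not pass without any 1 of the shRB arrays (adjusted p up to 0.113 and 0.142), nor did VIM, which also failed without shControl replicate 1 (up to 0.215). Blood and endothelial markers (11 measured, camera adjusted p = 0.9) had no gene past the threshold, with VWF at -0.65 (adjusted p = 0.164) and EMCN, which passed adjusted over the list alone, at 0.56 (adjusted p = 0.106).

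Cholesterol synthesis genes had the smallest list p (17 measured, 14 positive, median 0.22, camera adjusted p = 0.0977, or adjusted p = 0.888 with an estimated correlation). The sterol carrier STARD4 rose by 1.10 (adjusted p = 0.00862) and the isomerase IDI1 by 0.91 (adjusted p = 0.0398), and no further member passed, over all genes or over the list alone. The list passed after quantile normalization (adjusted p = 0.0468), without shControl replicate 1 (adjusted p = 0.0064) and without shRB replicate 1 (adjusted p = 0.0405). With an estimated correlation these became adjusted p = 0.912, 0.866 and 0.863. STARD4 did not pass without any 1 of the shRB arrays (adjusted p up to 0.0973), and IDI1 in none of the 5 fits (up to 0.197).

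Oxidative phosphorylation genes (14 measured, median 0.12, camera adjusted p = 0.31) had COX8A past the threshold adjusted over the list alone (log2 0.62, adjusted p over all genes 0.0976). That list passed after quantile normalization (adjusted p = 0.0468), but not with an estimated correlation as well (adjusted p = 0.912). Cytoplasmic ribosomal protein genes (29 measured, median -0.09, camera adjusted p = 0.29) had RPL38 at -0.34 (adjusted p = 0.263) and passed as a list without shRB replicate 1 (adjusted p = 0.0405), but not with an estimated correlation as well (adjusted p = 0.863). After quantile normalization the sign of their test turned (adjusted p = 0.88). Of 31 interferon-stimulated genes (camera adjusted p = 0.52), none passed over all genes, and the RNA sensor IFIH1 (0.53) and IFI35 (0.65) were higher and DDX60 (-0.54) lower adjusted over the list alone. In the endoplasmic reticulum stress (18 measured, camera adjusted p = 0.52), heat shock (10, 0.866), hypoxia and glycolysis (16, 0.782) and inflammatory factor (19, 0.866) lists no gene passed, over all genes or over the list alone.

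**Figure D3:**
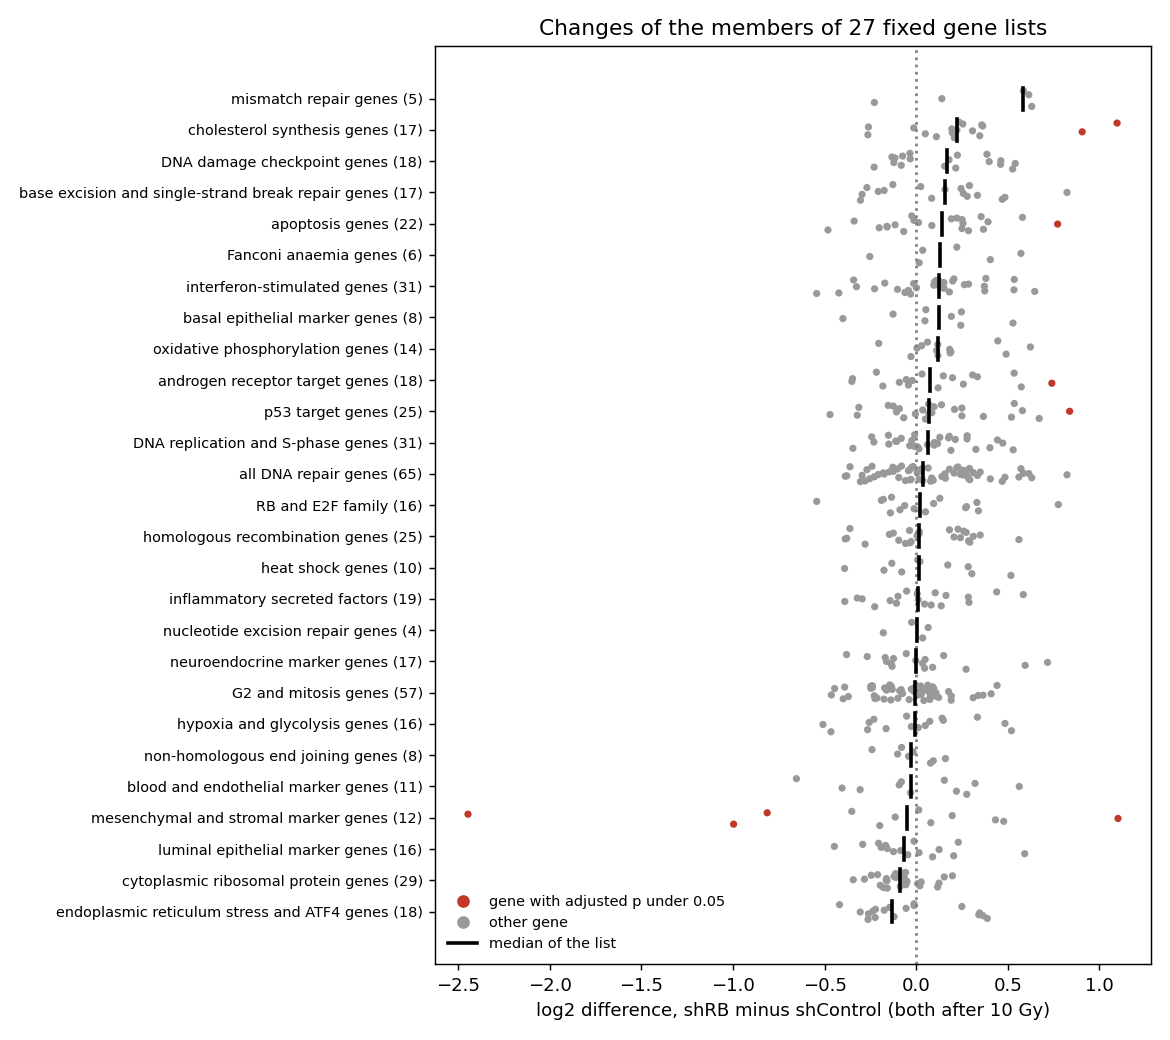
Log2 difference of shRB minus shControl (horizontal axis) for each measured member of the 27 lists (vertical axis, number measured in brackets), with 1 point per gene, red where the adjusted p is under 0.05, and black bars at list medians. Points past the threshold are TWIST1, FN1, VIM, SNAI2, STARD4, IDI1, PLK3, BIK and HERC3.

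Across the 27 lists, 0 passed with camera, 3 at an unadjusted p under 0.05 (cholesterol synthesis, mismatch repair and ribosomal proteins). With an estimated correlation 0 passed, with 0 at an unadjusted p under 0.05, and 0 passed by directional fry, with 7 at an unadjusted p under 0.05. By mixed fry, which asks for change in either direction and does not compare a list with other genes, 15 passed. They include all DNA repair (adjusted p = 0.0028), mismatch repair (0.0055), Fanconi (0.0027), homologous recombination (0.014), the checkpoint (0.00035) and replication (0.0017). The p53 target (0.001) and apoptosis (0.023) lists are also among them. So are the blood and endothelial (0.00088), mesenchymal (0.00088), interferon (0.0027) and androgen receptor target (0.0028) lists. The cholesterol synthesis (0.004), RB and E2F (0.029) and luminal (0.033) lists passed as well. The base excision, end joining, nucleotide excision and G2 and mitosis lists did not. Passing by mixed fry was thus not particular to repair or checkpoint genes. Of all genes tested, 18.12% had an unadjusted p under 0.05 (limma). The median, mean and test of the nucleotide excision, inflammatory and neuroendocrine lists differed in sign.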

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

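Probe sets without a gene name here were outside the comparison of genes, and some of them differed between groups. Of 28772 such probe sets, 117 were higher and 105 lower in shRB (limma on all probe sets, Benjamini-Hochberg). That is 0.772% of them, against 0.745% of the named probe sets in the same test. Probe set 16719786 had a log2 intensity of 5.13 in shRB and 10.46 in shControl, a difference of -5.32 (adjusted p = 2.2e-07), which is larger than that of any named gene. Probe set 17116675 stood at 5.19 in shRB and 8.96 in shControl (-3.78, adjusted p = 1.47e-05). In the other direction, probe set 16897493 differed by 1.52 (adjusted p = 0.00228) and probe set 17108914 by 1.37 (adjusted p = 0.0397). No explanation was tested, and the sequences they measure were not analysed here.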

How the results depend on the processing

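Removal of the constant of 16, and estimated correlations combined with another setting, were chosen after seeing the data. Against 103 genes higher and 56 lower in shRB, the counts were 197 and 90 without the lowest quartile of intensity, and 267 and 118 without genes below the median, where fewer genes were tested. Median subtraction gave 137 and 90, trend and robust variances 260 and 166, array weights 52 and 36, single probe sets 190 and 150, and an adjusted p under 0.10 gave 350 and 167. With 16 subtracted and 4 added, 4 were higher and 9 lower, or 294 and 156 with trend and robust variances. Quantile normalization (69 and 53) and averaged probe sets (88 and 51) stayed within 1.5 times. A 1.5-fold minimum (103 and 56) could remove no gene, as all that passed differed by more (smallest absolute log2 change 0.685). Beyond the filters, the cause was not tested. Leaving out 1 array gave 8 to 235 higher and 13 to 176 lower genes, RB1 differences of -0.60 to -0.49 (adjusted p 0.0959 to 0.305) and 0 to 2 lists past the threshold.

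RB1 passed in 1 alternative, at -0.54 (adjusted p = 0.0489) without genes below the median intensity. Quantile normalization put 2 lists past the threshold, cholesterol synthesis and oxidative phosphorylation (adjusted p = 0.0468, or adjusted p = 0.912 with an estimated correlation). The adjusted p without 1 array ranged over 0.149 to 0.913 for repair, 0.496 to 0.662 for apoptosis, 0.414 to 0.799 for replication and 0.249 to 0.687 for G2 and mitosis.

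The groups share replicate numbers, and deviations of equally numbered arrays correlated at -0.02 and 0.05. The deviations of the 2 shControl arrays mirror each other, so these values cannot show whether the numbers pair the arrays. With the replicate number as a block, 8 genes were higher and 16 lower, 24 in all, and RB1 differed by -0.53 (adjusted p = 0.319). No shControl array is numbered 3, so this block takes shRB replicate 3 out of the comparison. Without that array and with no block, 8 genes were higher and 14 lower and RB1 also differed by -0.53. The lower count under the block therefore cannot be put down to pairing.

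For the 24 largest changes, 321 of 356 values under alternatives kept direction and side of the threshold, 35 missed the threshold and 0 reversed. For 103 other named genes, 1419 of 1521 values kept their side of the threshold, 56 lost and 46 gained it and 0 passing values reversed. Most of these genes had not passed, so keeping their side meant staying short of the threshold. All 56 losses fell on those that had passed, BIK, FN1, HERC3, IDI1, PLK3, SNAI2, STARD4 and VIM. Each of these passed in only 6 to 10 of its 14 or 15 alternatives. Of the list tests 562 of 567 kept their side of the threshold and 5 gained a call. As no list had passed, none could lose a call, so this count says nothing on how stable a list result is. Quantile normalization ended the calls of BIK, FAM13A-AS1, IDI1 and TAB3, array weights those of BIK, HERC3, IDI1, PLK3, TAB3 and VIM, and averaged probe sets those of BIK, HERC3, TAB3, USP17L9P and VIM. Signs of results that passed in neither setting turned in 14 gene and 30 list values, which are counted above as keeping their side. Dim genes are limited by the floor of 16.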

Other observations

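Quantile normalization and the fits without 1 array were planned for the gene counts. The other tests in this part, those on chromosome 21 included, and the genes named outside the rule were chosen after the results had been seen. Several genes outside the lists fell in shRB. THBS1, thrombospondin 1, changed by -1.11 on the log2 scale (limma, adjusted p = 0.0139), while its relative THBS3 rose by 0.97 (adjusted p = 0.034). Decreases were also measured for the peroxidase PXDN of basement membranes (-1.13, adjusted p = 0.0102), reelin, RELN (-0.97, adjusted p = 0.0153) and IGF1R, the receptor of insulin-like growth factor 1 (-1.05, adjusted p = 0.0112). CAMK2N1, an inhibitor of calmodulin-dependent kinase, changed by -1.22 (adjusted p = 0.00264) and ASS1, an enzyme of arginine synthesis, by -0.80 (adjusted p = 0.0351). DDC, aromatic amino acid decarboxylase, rose by 1.14 (adjusted p = 0.00363), SOCS3 by 0.99 (adjusted p = 0.0101), the receptor NOTCH2 by 0.87 (adjusted p = 0.0257) and the transcription factor MYB by 0.86 (adjusted p = 0.0256).

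Further changes were in members of known gene families. The desmosomal cadherins DSG1 (log2 0.86, adjusted p = 0.0291) and DSC1 (0.88, adjusted p = 0.0452) and the protocadherin PCDHB15 (0.84, adjusted p = 0.0226) rose. Of 182 families of 10 or more genes with a common symbol stem, PCDH had the smallest p, with 3 of 15 members higher (PCDH7, PCDH20 and a member left out of naming). Fisher's exact test, two-sided, gave p = 0.000502 and did not pass after adjustment (0.0914). The desaturase FADS1 rose by 0.95 (adjusted p = 0.0139), while FADS2 (0.61, adjusted p = 0.0945) and FADS3 (0.70, adjusted p = 0.0563) did not pass and SCD5 changed by -0.81 (adjusted p = 0.031). The metallothionein MT2A, at 0.67 (adjusted p = 0.0708), did not pass.

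Most of these calls were lost when any 1 shRB array was left out. Such fits have fewer arrays, so a lost call does not show that the difference rests on that array. Of the 17 genes that passed and are named in this part outside the rule, BRWD1 of chromosome 21 included, 2 (CAMK2N1 and DDC) passed without shRB replicate 1 and 1 (CAMK2N1) without replicate 2 or 3. The others reached adjusted p-values of up to 0.22 in those fits, and DDC of 0.0587. Without shControl replicate 1, DSC1 did not pass (adjusted p = 0.0748), and without shControl replicate 2, ASS1, BRWD1 (adjusted p = 0.0577 for both) and THBS3 (0.0824) did not.

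Of the 159 genes past the threshold, 121 passed after quantile normalization, which argues against array scaling as the whole cause. Whether a single shControl array sets the calls cannot be told from the fits without shControl replicate 1 or 2. Those fits take the spread from the shRB arrays alone, which differed less from each other than the shControl arrays did. The 5 arrays can be split into 2 and 3 in 10 ways, of which 1, the real one, gave as many genes, and the highest other split gave 0. These splits are too few for a share under 0.05. Without shRB replicate 1, 2 or 3, 28, 22 and 22 of the 159 passed. Differences between the shRB and shControl populations other than RB1 level, such as selection of subclones, stay open and were not tested.

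The replication genes showed no shift past the threshold. A rise of 0.2 or more might be compressed by the constant of 16. With 16 subtracted and 4 added, the list's median per array was higher in shRB by 0.141 (SE 0.0575, 95% interval -0.0417 to 0.324, 3 against 2 arrays). The median of the genes' own changes was 0.0861 in that setting, against 0.0456 for all genes. The interval holds both 0 and 0.2, so a small rise and no rise cannot be told apart with 5 arrays.

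Genes of chromosome 21 were lower in shRB as a set. Of 79 protein-coding genes with a mean log2 intensity above 5, 67 (84.8%) were lower, with a median of -0.23 against 0.03 for other genes. The difference was -0.255, and the set lay lower in each of 3 shRB arrays than in both shControl arrays (permutation test over genes, two-sided, p = 1e-05, the smallest these permutations can give, adjusted p = 0.00023). Of the 23 chromosomes 5 passed, but no other differed by more than 0.0722, and genes are not independent replicates. Of the 79 genes 1, BRWD1, passed on its own.

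The lowest median among 10000 random lists matched on intensity was -0.13, which argues against an intensity bias. Over all 147 coding genes, dim ones included, the median was -0.11. A different dosage of chromosome 21 in the shRB and shControl cells is a candidate explanation that stays open, as does regulation of its genes by other means. Neither was tested, and DNA copy number was not analysed here.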
